A study of Homo sapiens with 4 samples.

How the data were processed

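Gene expression was measured in SAS, a line grown from a human oral squamous cell carcinoma, on 4 Affymetrix arrays. Per the labels' protocols, cells were infected with a retrovirus that expresses a short hairpin RNA (a transcript that folds back on itself and is processed into a small RNA that lowers a matching messenger). In the knockdown group the hairpin was directed at the HAI-1 gene, SPINT1, with the target sequence GGGCAGGCATAGACTTGAAGG, and in the control group it carried a scrambled form of it, GGGACGGAGATTTCACGAGGA. Each group holds 2 arrays. The place of the target sequence in the transcript was not analysed here, since no transcript sequence was used. Per the labels' protocols, biotin-labelled RNA was prepared from total RNA by a one-cycle protocol.

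The deposited values are MAS5 signals, that is probe set intensities on a linear scale, per the submitters' processing notes, which give no version. In the deposited table each array has a 2%-trimmed mean signal close to 500 (between 499.912 and 499.917) and signals below 1 are set to 1. MAS5 subtracts background before these signals are formed, so the background correction could not be changed here. The deposited detection p-value and call (present, marginal or absent) of each probe set on each array were taken as given. The deposited log2 columns hold the log2 signal less each probe set's median over the 4 arrays: recomputing them from the signals gave all 54675 rows within a tolerance of 1e-05, and the separate deposited table of log2 values held the same numbers. Their medians per array were 0.02, 0.01, -0.02 and -0.01 for knockdown 1, knockdown 2, control 1 and control 2. The software behind that step and the genome build of the alignments are not given in the sources used here.

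Probe sets were named through the Entrez gene number in the deposited annotation, updated to current symbols with the gene table of assembly GRCh38.p14, of which no coordinate was used. Of the 54613 probe sets outside the array's 62 controls, 39614 were named in this way, 1093 kept the symbol of the file, 1044 stand for several genes and were not named, and 12862 had no gene. The update changed 6616 symbols. A gene's value is that of its probe set with the highest mean over the 4 arrays among those that map to that gene alone.

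Signals were used as log2(signal + 16), with no further scaling between arrays, so fold changes of dim probe sets are understated. Probe sets whose mean lay at or above the median of all probe sets (a signal of 55.4) were tested, 27307 in all, for 12574 genes. The test was limma's moderated test (two-sided, lmFit and eBayes with a mean-variance trend, limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. All 4 arrays entered the fit with 2 residual degrees of freedom and a prior of 9.04. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so the p-values rest on the variance model. The labels do not say that the arrays come from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

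Gene lists were compared with all other genes tested by limma's camera (two-sided, preset correlation between genes of 0.01), adjusted over 19 pathway lists: the matriptase-HAI system, epithelial junction, mesenchymal, EMT transcription factors, keratinocyte differentiation, basal squamous, matrix proteases and inhibitors, TGF-beta response, inflammatory cytokines and NF-kB targets, interferon response, EGFR ligands and MAPK feedback, cell cycle, p53 targets, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol synthesis, Wnt targets, Notch pathway, and integrins and laminins. Lists of leukocyte, endothelial and fibroblast markers and of housekeeping genes were adjusted apart. Lists with fewer than 5 genes tested were only counted.

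The genes named are SPINT1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap (unnamed loci, numbered open reading frames and antisense genes passed over), up to 4 members of each list with the largest moderated statistic, and a fixed set of 11 genes of the protease system and of epithelial and mesenchymal state. Not all genes chosen by this rule are reported here. Lists, tests, this rule and the other settings named below were set before the data were examined. The list statistic that sets a list's mean change against that of all other genes was added after the results had been seen, and so was the setting that leaves out genes of shifted chromosome stretches. A gene called present on no array of 1 group has only a bound on its fold, written "at least", formed against the lowest signal called present on each array of that group, or the gene's own signal where that was higher. The bound is formed from group means and concerns detection only. It does not allow for the spread between arrays, so it is not a lower confidence limit.

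Neighbouring genes were compared by placing 12491 genes at the first alignment in the deposited annotation and dividing each chromosome into runs of 30 genes. Genes left over at the end of a chromosome entered no run. The limit on a run's median log2 change, less that of all genes placed, was the highest absolute run median that 95% of 1000 genomes with shuffled gene order stayed under. A probe set with several alignments may be misplaced by this rule, so the runs were formed again with the highest-scoring alignment, a setting added after the results had been seen.

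The tests were also run on simulated data. Normal noise was drawn with the variances that the fit had given the real signals, and 27307 probe sets were tested. The fit recovered 27.3% of 66 changes of 1.50-fold, 78.1% of 64 changes of 2-fold and 100% of 61 changes of 4-fold. Of its 150 calls 5.33% were unchanged probe sets. In 20 further draws, added after the results had been seen, the median recovery of 1.50-fold changes was 45.1% (36.9% to 57.8%, all above the first draw) and of 2-fold changes 81.4% (70.8% to 92.1%), and the unchanged share of calls had a median of 6.01% (2.52% to 10.1%). Of the lists, 1 was called, the shifted one. Since the noise came from the fit's own variances, the variance model itself was not tested. Fewer changes were planted than the 4244 probe sets called in the real data, so recovery may differ there. The simulated noise was independent between probe sets. Lists whose genes vary together, such as cholesterol synthesis with an estimated correlation of 0.29 in the real data, were therefore not tested by it. In 20 simulated genomes of 12491 genes, 40 of 40 runs inside a stretch of 90 genes shifted by -0.6 on the log2 scale lay beyond the limit and 1 of the 20 unshifted genomes held such a run.

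The alternatives were pseudocounts of 1 and 64, no filter, an upper quartile filter, a filter on detection calls, quantile normalization, median centring, eBayes without the trend, the experiment number as a block, leaving out each array, other thresholds, genes as the unit, other probe sets per gene, an estimated correlation and limma's fry. With an estimated correlation camera rests on the fit's 2 residual degrees of freedom, so few lists could pass. A miss under that setting therefore does not by itself point to correlation between genes. Fry asks whether a list's genes shifted together in 1 direction, while camera sets them against all other genes. Figures were drawn with matplotlib 3.10.9. A search for hairpin seed matches was not made, since no untranslated region sequences were used here.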

Results

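The transcriptome of SAS oral squamous carcinoma cells with the HAI-1 gene silenced was compared with that of cells given a scrambled hairpin, on 2 arrays per group. HAI-1 is a membrane-bound inhibitor of trypsin-like serine proteases on epithelial cells, matriptase among them. The comparison addresses which transcripts differ when HAI-1 is lowered in these cells. Of all probe sets on the array, 48.1% and 45.6% were called present on knockdown arrays 1 and 2, and 46.5% and 46.4% on control arrays 1 and 2. Over the probe sets tested, Pearson's r across probe sets, which are not independent replicates, was 0.983 between the knockdown arrays and 0.987 between the control arrays, and it lay between 0.961 and 0.964 across groups.

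SPINT1, which encodes HAI-1, fell to 14.4% of the control signal. Its main probe set (chromosome 15, 38923565 to 38937145, plus strand, genome build not named in the sources used here) gave 209 ± 103 (SD, n = 2) in knockdown cells and 1448 ± 4.45 (SD, n = 2) in control cells, a log2 change of -2.79 (SE 0.25, adjusted p = 4.2e-05). The knockdown arrays read 135 and 282 and the control arrays 1451 and 1445, and the gene was called present on 1 of the 2 knockdown arrays and on both control arrays. The other SPINT1 probe set (chromosome 15, 38937191 to 38937879) was not called present on any array, and its log2 change of -0.11 (SE 0.22) had an adjusted p of 0.79.

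ST14, which encodes matriptase, had a log2 change of 0.15 (SE 0.12, adjusted p = 0.45), PRSS8, which encodes prostasin, one of -0.17 (SE 0.22, adjusted p = 0.66), and SPINT2, which encodes the related inhibitor HAI-2, one of -0.16 (SE 0.10, adjusted p = 0.36). None of these passed the limma test. F2RL1, which encodes the protease-activated receptor PAR-2, rose from 4555 ± 302 to 6125 ± 14.6 (SD, n = 2 each, adjusted p = 0.017), but its adjusted p was 0.086 without control array 1 and 0.23 without control array 2, and it also missed the threshold without the filter (0.064) and without the variance trend (0.14). The other F2RL1 probe set had a log2 change of 0.06 (adjusted p = 0.86). PLAU, which encodes the urokinase-type plasminogen activator, rose 1.99-fold (adjusted p = 0.00015). Of 19 members tested in the matriptase-HAI list, 3 rose, 1 fell and 15 did not pass. Adjusted over the list alone, 4 rose and 1 fell, and the list as a whole did not pass (adjusted p = 0.32).

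**Figure D1:**
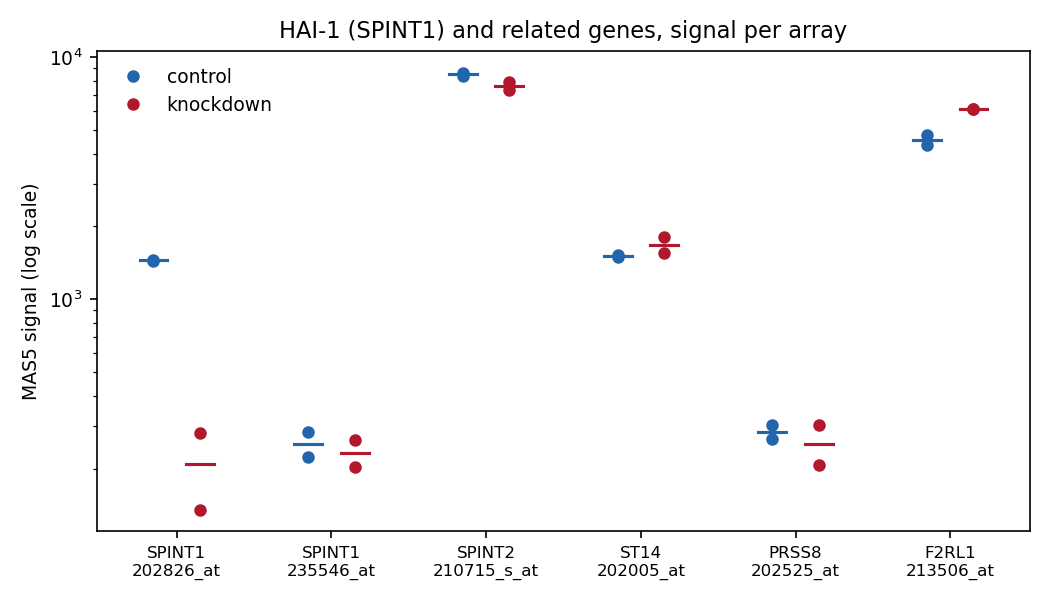
MAS5 signal (log scale) of both SPINT1 probe sets and of SPINT2, ST14, PRSS8 and F2RL1; each point is 1 array, control in blue and knockdown in red, and each bar a group mean of 2 arrays. The main SPINT1 probe set lies at 135 and 282 in knockdown cells against 1451 and 1445 in control cells, while the probe sets of SPINT2, ST14 and PRSS8 lie close together in both groups.

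The groups differed widely beyond the target. Keratin 14 (KRT14), a basal keratinocyte keratin, rose 16.7-fold, from 89.5 ± 23.7 to 1731 ± 219 (SD, n = 2 each, adjusted p = 6.7e-07), and follistatin (FST), a secreted activin antagonist, rose 16.5-fold, from 487 ± 46.0 to 8324 ± 1199 (adjusted p = 3.2e-08). Cyclin D2 (CCND2), a G1 cyclin, fell from 9260 ± 199 to 326 ± 72.0 (27.4-fold, adjusted p = 2.3e-08). Ubiquilin 2 (UBQLN2), a ubiquitin-binding shuttle protein, and keratin 23 (KRT23) were called present on both control arrays and on no knockdown array, and were at least 133-fold and at least 41.7-fold lower in knockdown cells (adjusted p = 1.2e-08 and 1.3e-06).

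Among the other large rises, PLAC8 increased 15.3-fold, the placental alkaline phosphatase gene ALPP 12.3-fold and the glutathione transferase gene GSTM3 12.2-fold. ALPP has a near-identical copy, ALPG, so its signal is uncertain as to gene, and the second GSTM3 probe set tested had a log2 change of 0.12 (adjusted p = 0.86). Several genes were called present, on their brightest probe set, on both knockdown arrays and on no control array: the epidermal barrier gene FLG (filaggrin) was at least 17.6-fold higher, the receptor phosphatase gene PTPRG at least 12.7-fold, the glypican gene GPC4 at least 9.60-fold, the galanin gene GAL at least 9.16-fold, the fatty acid oxidation gene CPT1A at least 8.74-fold and the receptor gene LPAR6 at least 7.69-fold. The log2 change of GPC4 was 3.96 without control array 1 and 2.72 without control array 2, against 3.34 with all arrays. The second GAL probe set, under the filter and called present on 1 array of each group, had a log2 change of -0.27. Other CPT1A probe sets tested, called present on both knockdown arrays and on no control array, had log2 changes of 1.68 and 1.66 (adjusted p = 0.0091 and 0.0055). These lay below the 3.13 of its brightest probe set. CPE, which encodes carboxypeptidase E, read 903 ± 47.0 in knockdown and 16.3 ± 4.03 in control cells (SD, n = 2 each, adjusted p = 8.6e-07), but its brightest probe set was not called present on any array, so no fold is given. The second CPE probe set, called present on both knockdown arrays and on 1 control array, had a log2 change of 3.84 (adjusted p = 1.0e-05). The adjusted p of the other rises in this group lay between 3.8e-08 (ALPP) and 0.00035 (LPAR6).

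Among the falls, NICOL1 was at least 70.6-fold lower, KANK4 at least 21.7-fold, the procollagen-processing protease gene ADAMTS2 at least 10.3-fold and CRACDL at least 6.75-fold, each called present on no knockdown array. ADAMTS2 read 9.11 and 68.1 on the knockdown arrays, and its log2 change of -3.37 was -2.50 without knockdown array 1 and -4.24 without knockdown array 2. Without knockdown array 1 its fall was thus smaller than the bound given. The amino acid transporter gene SLC6A15 decreased 16.9-fold and the autophagy kinase gene ULK2 7.31-fold, both called present on 1 of the 2 knockdown arrays. The log2 change of ULK2 was -3.47 without knockdown array 1 and -2.27 without knockdown array 2, against -2.87 with both. The other ULK2 probe set tested, called present on all 4 arrays, had a log2 change of -0.73 and did not pass (adjusted p = 0.11). SEL1L3 decreased 8.71-fold and PWWP3B 7.29-fold. The adjusted p of these falls lay between 5.3e-08 (NICOL1) and 0.00054 (ADAMTS2). NICOL1, SEL1L3 and GPC4 lie in the shifted chromosome stretches described further on.

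In all, 4244 of 27307 probe sets passed the limma test (15.5%), 1977 higher and 2267 lower in knockdown cells. By genes, 2419 of 12574 passed, 1093 higher and 1326 lower. Changes of at least 2-fold were called for 540 probe sets higher and 658 lower, and of at least 4-fold for 84 and 71. The groups did not overlap for 57.6% of the probe sets tested, against 33.3% by chance. With each array centred on its median the calls were 4324, and 34.9% of them were higher in knockdown cells against 46.6% as reported. Without control array 1 the test called 2200 probe sets and without control array 2 it called 2500, the remaining control array being assumed to vary like the others; without the filter it called 2211 and without the variance trend 1517.

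Most members of the hypoxia and glycolysis list rose, but its glycolysis genes were not tested apart. Of 29 members tested, 18 rose, none fell and 11 did not pass, and adjusted over the list alone 20 rose. CA9, a carbonic anhydrase gene induced at low oxygen, rose 6.18-fold, from 89.6 ± 22.7 to 633 ± 115 (SD, n = 2 each, adjusted p = 3.4e-05). BNIP3, a mitophagy gene, rose 2.60-fold (adjusted p = 4.9e-05), the stress gene NDRG1 2.27-fold (adjusted p = 3.6e-05) and the adrenomedullin gene ADM 1.88-fold (adjusted p = 0.00019). VEGFA, at a log2 change of 0.42 (adjusted p = 0.055), and the glycolytic genes LDHA (0.23, adjusted p = 0.26) and ENO1 (0.11, adjusted p = 0.57), named after their values were seen, did not pass. The list's median log2 change was 0.51 and its mean exceeded that of all other genes by 0.72. It passed limma's camera test (adjusted p = 1.6e-10), with adjusted p = 0.31 with an estimated correlation.

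Genes of cholesterol synthesis fell. Of 22 members tested, none rose, 13 fell and 9 did not pass; adjusted over the list alone 16 fell. INSIG1, which encodes a sterol-regulated retention protein of the endoplasmic reticulum, fell 4.84-fold, from 4585 ± 469 to 947 ± 239 (SD, n = 2 each, adjusted p = 8.6e-06). The synthase gene HMGCS1 fell 3.60-fold (adjusted p = 1.5e-05) and NSDHL, which lies in a shifted stretch of chromosome X, fell 2.60-fold (adjusted p = 0.00040). The median log2 change was -0.53 (camera adjusted p = 8.8e-09; adjusted p = 0.60 with an estimated correlation).

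Inflammatory cytokines and NF-kB targets fell as well, with 9 of 17 members tested lower, none higher and 8 not past the test. Adjusted over the list alone, 9 fell and 1 rose. IL6 fell from 1437 ± 213 to 526 ± 3.80 (2.67-fold, SD, n = 2 each, adjusted p = 7.5e-05), the interleukin 1 alpha gene IL1A fell 2.44-fold (adjusted p = 0.00043) and TNFAIP2 fell 2.43-fold (adjusted p = 1.6e-05). The chemokine gene CCL20, called present on 1 control array and on no knockdown array, was at least 3.82-fold lower (adjusted p = 0.00075). The median log2 change of the list was -0.68 (camera adjusted p = 6.2e-06; adjusted p = 0.60 with an estimated correlation).

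Keratinocyte differentiation genes passed by a smaller margin, with 6 of 22 members higher, none lower and 16 not past the test. Adjusted over the list alone, 7 rose and 3 fell. Besides FLG, the antimicrobial gene S100A7, called present on no control array, was at least 5.71-fold higher (adjusted p = 0.00043), and the cornified envelope gene PPL and the transcription factor gene GRHL1 rose 2.12-fold and 1.84-fold (adjusted p = 0.00014 and 0.0020). The median log2 change was 0.43 (camera adjusted p = 0.030; adjusted p = 0.60 with an estimated correlation). Without knockdown array 2 the adjusted p of the list was 0.094, and it also missed the threshold with no filter (0.10), with the upper quartile filter (0.17) and with the mean over each gene's probe sets (0.052).

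**Figure D2:**
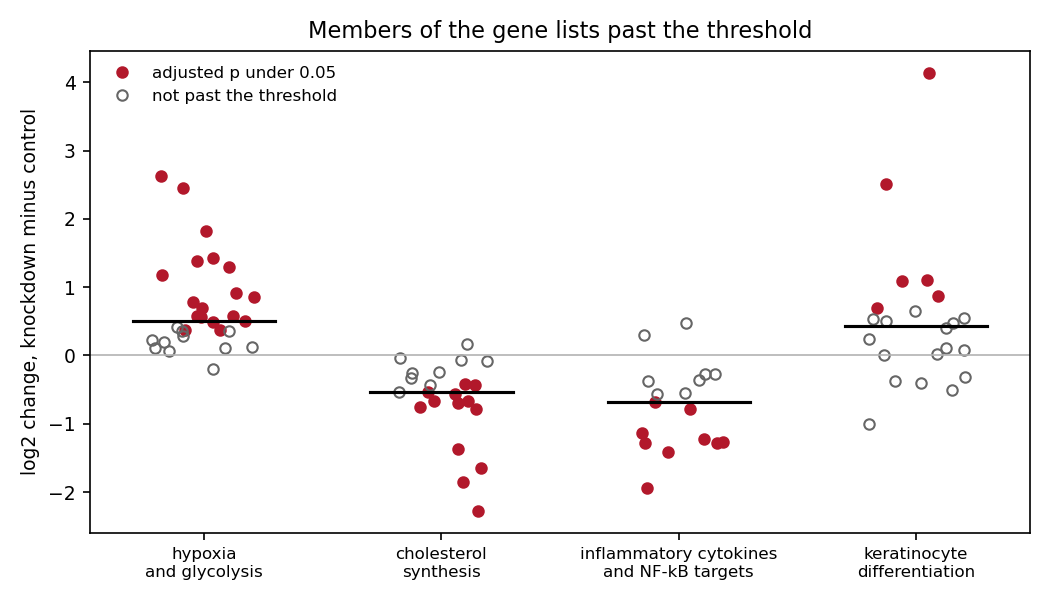
Log2 change (knockdown minus control) of each tested member of the 4 gene lists past the camera threshold at the preset correlation. With an estimated one, which rests on 2 residual degrees of freedom, 0 lists passed. Filled points passed the limma test, open points did not, and each bar is the list median. The medians are 0.51 for hypoxia and glycolysis, -0.53 for cholesterol synthesis, -0.68 for inflammatory cytokines and NF-kB targets and 0.43 for keratinocyte differentiation.

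Epithelial and mesenchymal genes did not move as groups. CDH1, which encodes E-cadherin, had a log2 change of 0.33 (SE 0.11, adjusted p = 0.077; 0.017 without knockdown array 2) on its brightest probe set and -0.21 (adjusted p = 0.68) on another. VIM, which encodes vimentin, was called present on 1 of 2 arrays in each group, at 0.42 (SE 0.38, adjusted p = 0.51), and SNAI2 stood at 0.25 (SE 0.12, adjusted p = 0.21). TWIST1, a transcription factor of epithelial-mesenchymal transition, fell 1.90-fold (adjusted p = 0.0033), with an adjusted p of 0.053 without the variance trend. SNAI1 and ZEB1 were called present on no array and ZEB2 on 1 control array, and all 3 lay under the filter. The junction genes PKP1 and CLDN3, named after their values were seen, also lay under the filter and were not tested. PKP1 was called present on both knockdown arrays and on no control array, at least 8.20-fold higher. CLDN3 was called present on no array. In the epithelial junction list 4 of 36 rose, among them the claudin gene CLDN7 (1.94-fold, adjusted p = 0.00081; 0.055 without the variance trend), and 3 fell, among them the desmoglein gene DSG3 (2.03-fold, adjusted p = 0.00066); adjusted over the list alone 6 rose and 5 fell (camera adjusted p = 0.39). Of 19 mesenchymal genes 2 rose and 4 fell, with ACTA2, a smooth muscle actin gene, down 3.26-fold (adjusted p = 4.3e-05) and FAP down 1.86-fold (adjusted p = 0.00028); adjusted over the list alone 3 rose and 5 fell (camera adjusted p = 0.45). Of 7 transcription factors of this transition 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.45).

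Single genes moved strongly in lists that did not pass as wholes. In the TGF-beta list 7 of 26 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.46): ID2, which encodes an inhibitor of helix-loop-helix transcription factors, rose 2.66-fold (adjusted p = 0.00047). Of 27 EGFR and MAPK feedback genes 8 rose and 7 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.98), with the ligand gene EREG down 2.63-fold (adjusted p = 3.7e-05) and the ligand gene TGFA up 1.79-fold (adjusted p = 0.00043). Of 26 unfolded protein and amino acid stress genes none rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.33). ATF3 fell by 3.51-fold (adjusted p = 1.0e-05) and the amino acid transporter gene SLC3A2 by 2.60-fold (adjusted p = 1.6e-05). In the shifted chromosome stretches lay 5 members of this list, 3 of them called. Without the genes of those stretches none rose and 4 of 21 fell, with a median log2 change of 0.12 (camera adjusted p = 0.60). Of 24 p53 targets 2 rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.32), with CCNG1 down 3.04-fold (adjusted p = 4.0e-06) and FAS down 2.03-fold (adjusted p = 0.00021).

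Of 21 basal squamous genes 2 rose and 4 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.33); beside KRT14, KRT5 rose 2.62-fold (adjusted p = 0.00027), and the growth factor receptor gene NGFR, called present on 1 of 2 knockdown arrays, fell 3.60-fold (adjusted p = 0.00045). Of 21 matrix proteases and inhibitors 4 rose and 2 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.91), with the inhibitor gene TIMP3 up 2.60-fold (adjusted p = 0.00016) and ADAMTS1 down 4.03-fold (adjusted p = 1.9e-05). Of 28 interferon response genes 3 rose and 2 fell, in both adjustments (camera adjusted p = 0.39), with IFI6 up 2.27-fold (adjusted p = 0.0012) and SAMD9, in a shifted stretch of chromosome 7, down 2.39-fold (adjusted p = 2.6e-05). Of 36 cell cycle genes 6 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.32), MCM7 among the latter (2.10-fold, adjusted p = 0.00039). Of 12 Notch pathway genes 3 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.55), and HES2, called present on 1 of 2 control arrays, rose 3.82-fold (adjusted p = 0.00035). Of 23 integrins and laminins 2 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.32), with LAMA4 down 2.96-fold (adjusted p = 0.00012). None of 10 Wnt targets passed (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.999). Median, mean and test differed in sign for the basal squamous genes (median -0.16, mean 0.06, test lower), the matrix proteases (-0.04, -0.0039, test higher), the EGFR and MAPK genes (0.0092, -0.06, test lower), the stress genes (0.04, -0.21, test lower) and the Wnt targets (-0.03, -0.01, test higher).

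Of the leukocyte markers LAPTM5 rose among 7 tested (2.52-fold, adjusted p = 0.023), of 5 endothelial markers CDH5 and TEK rose (1.93-fold and 1.99-fold, adjusted p = 0.021 and 0.029), and of 3 fibroblast markers FBLN1 rose (1.74-fold, adjusted p = 0.0048; 0.055 without the variance trend) and FAP fell; the counts adjusted over each list alone were the same. The calls of LAPTM5, CDH5 and TEK did not hold without single arrays: without knockdown array 2 the adjusted p was 0.052 for LAPTM5 and 0.085 for CDH5, and without knockdown array 1 it was 0.12 for LAPTM5 and 0.15 for TEK; without control array 1 it was 0.13 for LAPTM5 and 0.11 for TEK, and without control array 2 it was 0.068 for TEK. LAPTM5 and TEK were called present on 1 of the 2 control arrays, and the log2 change of CDH5 was 0.49 without knockdown array 2 against 0.94. The leukocyte and endothelial lists did not pass camera (adjusted p = 0.86 and 0.42), but the endothelial list passed fry (adjusted p = 0.029), and its median log2 change over 5 genes lay between 0.32 and 0.37 in the 4 pairings of a knockdown with a control array. The leukocyte list did not pass fry (adjusted p = 0.24), and the leukocyte gene PTPRC was called present on no array. Of 18 housekeeping genes 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.99; median 0.06, mean -0.02, test higher). Among them SDHA fell 2.04-fold (adjusted p = 9.8e-05) and HPRT1, in the shifted stretch of chromosome X, fell 1.49-fold (adjusted p = 0.0063; 0.12 without control array 1 and 0.055 without control array 2). The first alignment of the SDHA probe set lies on chromosome 3, but its highest-scoring one lies in the lower stretch of chromosome 5. ACTB and GAPDH had log2 changes of 0.04 (adjusted p = 0.91) and 0.07 (adjusted p = 0.79).

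Changes were not spread evenly over the chromosomes. Of 404 runs of 30 neighbouring genes, 29 had a median log2 change, less that of all genes placed, beyond the limit of 0.33 set by shuffled gene order, 22 lower and 7 higher in knockdown cells. Medians of whole stretches are given here without that subtraction. On chromosome 4, from 43226 to 48603557 in the alignments of the files, 5 adjoining runs with 150 genes had a median log2 change of -0.81, with 96 genes called lower and 4 higher. On chromosome X, 90 genes from 119127038 to 153360445 had a median of -0.67 (52 lower, 6 higher), and on chromosome 5, 90 genes from 209204 to 42837926 had one of -0.54 (55 lower, 3 higher). Chromosome 7 held 9 such runs in 4 stretches, the first, from 30430674 to 64503475, with a median of -0.48, and 192 of its 594 genes were called lower against 23 higher. Higher stretches lay on chromosome 3, from 3143634 to 25681398 (median 0.46, 41 of 90 genes called higher), and on chromosome 13, from 52124883 to 107658458 (median 0.40, 26 of 60 called higher). In each of the 4 pairings of a knockdown with a control array the median of the chromosome 4 stretch lay between -0.77 and -0.74. Of the genes in the 29 runs 52.9% were called, against 16.8% of genes outside. These 29 runs held 870 of the 12491 genes placed and 460 of the 2409 called genes that were placed (19.1%). None of the hypoxia and keratinocyte list members tested lay in them, 1 of the cholesterol list did (NSDHL) and 1 of the inflammatory list did (RELB, named after its place was seen). INSIG1, on chromosome 7 at 154720357, entered no run. It lies past the last run of that chromosome, which ends at 150566841 and is among the lower ones. IL6 and TWIST1 also lie on chromosome 7, in a run within the limit (median less that of all genes placed -0.16). So does MCM7, in another run of chromosome 7 within the limit (-0.16).

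**Figure D3:**
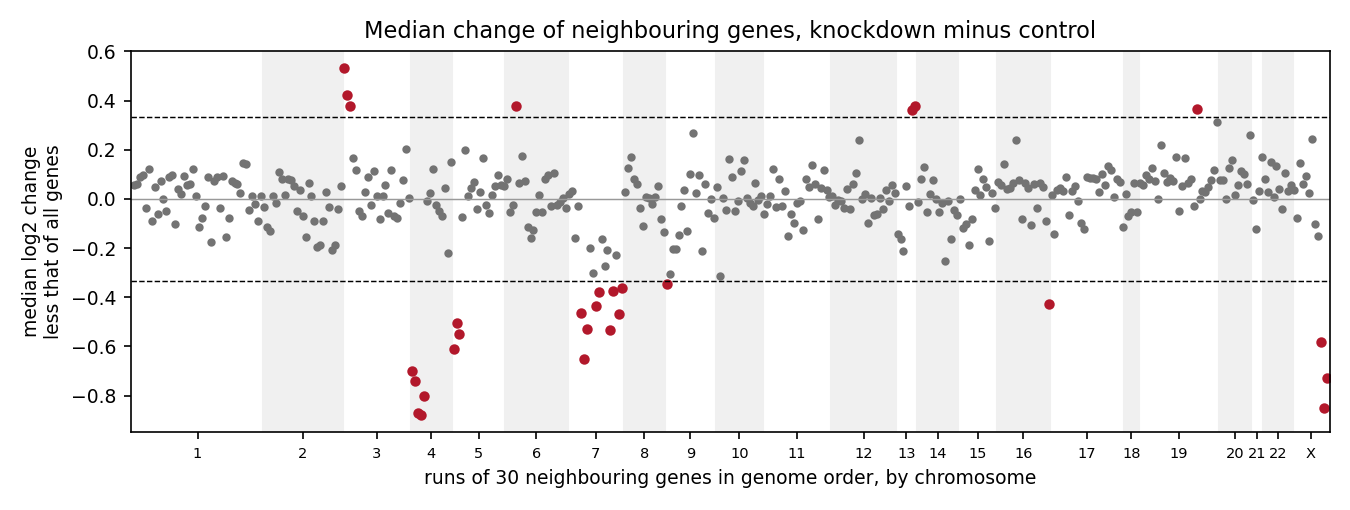
Median log2 change (knockdown minus control, less that of all genes placed) of runs of 30 neighbouring genes along the chromosomes; each point is 1 run, dashed lines mark the limit of 0.33 on either side, and red points lie beyond it. The red points cluster on chromosomes 4, 5, 7 and X below the lower line and on chromosomes 3 and 13 above the upper line.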

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

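The setting without the genes of shifted chromosome stretches and the placement by highest-scoring alignment were chosen after the data had been seen. SPINT1 stayed lower and past the threshold in all 14 alternatives run for it, with log2 changes from -3.27 to -2.30 and adjusted p from 4.8e-08 to 0.025. Calls numbered 2211 with no filter (921 higher, 1290 lower; more probe sets were tested), 1517 without the variance trend (630 higher, 887 lower), 1359 for 2-fold changes with groups apart and 2419 by genes. Leaving out 1 array gave 2200 to 4751 calls, 1036 to 2197 higher and 1164 to 2579 lower. Without the genes of shifted stretches 3299 were called, 1721 higher and 1578 lower. Placing genes at their highest-scoring alignment moved 461 genes and gave 30 runs beyond the limit, 5 higher and 25 lower, on 9 chromosomes. The experiment numbers do not pair the arrays by the labels, and the deviations of same-numbered arrays correlated at -0.026; with the replicate block 4365 probe sets were called, and PGK1 lost its call and LEF1 gained one (adjusted p = 0.063 and 0.039) among the genes named. Every probe set called both as reported and under any of these settings kept its direction. With an estimated correlation, a setting that rests on 2 residual degrees of freedom, 0 lists were called. Fry, which does not set a list against other genes, called 3 of camera's 4, without cholesterol synthesis (adjusted p = 0.054). The lists that turned direction had not passed the test, and their mean change less that of other genes was, for mesenchymal genes, 0.0046 with pseudocount 1, 0.052 with no filter and 0.067 with the mean over probe sets; for matrix proteases 0.0013 with pseudocount 64, 0.020 with no filter, 0.028 with the upper quartile filter, 0.0027 without knockdown array 2, 0.040 without control array 1 (-0.051 without control array 2), 0.021 with the mean over probe sets and 0.060 without cross-hybridizing probe sets; for Wnt targets 0.089 with no filter, 0.050 with the upper quartile filter, 0.056 without knockdown array 2 (-0.084 without knockdown array 1), 0.016 without control array 2, 0.033 with the mean over probe sets and 0.14 without cross-hybridizing probe sets; for housekeeping genes 0.0022 with the upper quartile filter, 0.066 without knockdown array 1 (-0.10 without knockdown array 2) and 0.080 without cross-hybridizing probe sets; for the Notch pathway -0.039 with the upper quartile filter; for TGF-beta -0.074 without cross-hybridizing probe sets; and for basal squamous genes -0.035 without knockdown array 2 and -0.021 without control array 2. PRSS8 stood at 0.089 without knockdown array 1 and -0.42 without knockdown array 2, and PECAM1 at -0.62 and 0.27. Other probe sets of a gene went the other way for CDH1 (-0.21), TCF3 (-0.95), EGFR (0.30), ERBB3 (-0.042 and -0.037), ITGB8 (0.28), ITGA2 (0.69, past the threshold), COL1A1 (1.20, past the threshold) and CD44 (0.032, 0.18, 0.21, 0.22, 0.20, 0.16 and, past the threshold, 0.75). The cause was not tested. A block by slide or scan date was not run, since the sources used here give none. Dim signals limit folds below the present calls.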

Other observations

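The comparison of runs with shuffled gene order was planned before its result was seen; the tests of RNA quality, of calls on other chromosomes, of the lists without shifted stretches, of second probe sets and of the pairings of arrays were chosen after the results had been seen. Beyond the stretches on chromosomes 3, 4, 5, 7, 13 and X, single runs were lower on chromosomes 9 (666887 to 17158620, median log2 change less that of all genes placed -0.35) and 16 (82713388 to 87450841, -0.43). Single runs were higher on chromosome 6 (26232380 to 28165317, 0.38), which opens at the histone gene H2AC6, and on chromosome 19 (48927147 to 50348869, 0.37); these genes were named after their place was seen. GPC4 rose although it lies in the stretch of chromosome X whose median fell by 0.67 on the log2 scale.

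The first pattern is the large number of calls. A scaling difference between arrays was argued against by quantile normalization, which gave 4339 calls. A difference in RNA quality was argued against by the signal ratios from the 3' to the 5' end of the GAPDH and ACTB transcripts: 0 of the 2 separated the groups (ACTB 1.47 and 1.86 in knockdown, 1.60 and 1.57 in control). For the runs of neighbouring genes, 29 lay beyond the limit, which is consistent with a difference in chromosome copy number between the infected populations as a hypothesis for those genes; shuffled order does not account for neighbours that are regulated together, and no DNA was measured. Inside the runs, which were picked by their shifted medians, 52.9% of genes were called, against 16.8% of genes outside them. On the chromosomes without such a run 16.2% of genes were called, against 19.3% over all genes placed. The runs held 870 of the 12491 genes placed and 19.1% of the called genes. A direct effect on the genes of these runs therefore does not cover most calls. Shifts under the limit, and effects of the shifted genes on genes elsewhere, were not tested, so a copy number difference is not excluded for the other calls. Whether such a difference came with the knockdown, with the infection or with the cells each virus entered cannot be separated in this design of 1 hairpin per group, and the silencing of HAI-1 stays open, untested, for the remaining calls.

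The second pattern is the gene lists. All 4 lists stayed past the camera threshold in the same direction without the genes of shifted stretches. These stretches held at most 1 tested member of each list (2 of cholesterol synthesis by highest-scoring alignment), so leaving them out could change little. The result argues only against the members' own place in these stretches as the source. INSIG1, which entered no run, was not left out. An effect of the shifted genes on list members elsewhere was not tested. With an estimated correlation 0 lists passed, but that setting rests on 2 residual degrees of freedom and could pass few. For hypoxia and glycolysis the estimate was -0.028, below the preset 0.01, yet camera's unadjusted p went from 8.2e-12 to 0.016. For cholesterol synthesis the estimate was 0.29, above the preset. The setting thus cannot tell whether correlation between genes accounts for the list results. Fry did not call cholesterol synthesis (adjusted p = 0.054). A culture difference in 1 of the experiments was looked for in the 4 pairings of a knockdown with a control array. The smallest median log2 change was 0.49 for the hypoxia and glycolysis genes, against a list median of 0.51. For the cholesterol synthesis genes the smallest fall gave -0.46, against -0.53. Most members of both lists had passed limma's test on these same arrays, which already asks arrays of a group to agree. The pairings therefore could not decide this question. A difference in density or medium shared by both experiments was not tested and stays open beside the silencing of HAI-1.

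The third pattern is the set of 23 genes past the threshold whose fitted change was at least 8-fold. Among them are genes given above with only a bound, such as LPAR6 (at least 7.69-fold), and CPE, for which no fold was given. Of 9 genes with a second probe set tested, 8 moved the same way past the threshold on the next brightest one (88.9%), among them CCND2, FST and CPE. For these 8 genes this argued against a sequence variant, transcript form or cross-hybridization at 1 probe set. The exception was GSTM3, at 0.12 on its second probe set. Second probe sets were tested only if bright enough for the filter, so the share does not extend to all 23 genes. Among the genes named, PTPRG, LPAR6, GAL and ADAMTS2 had other probe sets only under the filter. Their log2 changes there were 0.49 and -0.035 for PTPRG, 0.14 for LPAR6, -0.27 for GAL and -0.61 for ADAMTS2. UBQLN2, NICOL1 and the other genes without a second probe set tested were not covered by this test, so for them the explanation stays open.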
